A study of Homo sapiens with 16 samples.

How the data were processed

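Total RNA of C3A cells, a clonal derivative of the human hepatoma-derived line HepG2, was measured on one-colour (Cy3) Agilent oligonucleotide arrays, 1 array per RNA sample and 16 arrays in all. Per the labels, cells were seeded at 250000 cells per ml, incubated for 24 h and exposed for 2 h, 6 wells were pooled for each RNA sample, and 0.1% DMSO was the solvent control. The labels state no doses and do not spell out the abbreviation TCP. Groups were taken from the sample titles: benzo[a]pyrene, CCCP, FCCP, dinoterb and TCP with 2 arrays each, and DMSO control and medium control with 3 arrays each.

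Per the file headers, the authors' scans were quantified with Agilent Feature Extraction 10.7.3.1, with background subtraction, spatial detrending and multiplicative detrending, and probe positions on build hg19 (GRCh37). Per the file headers, the processed signal is the linear intensity of each spot after the authors' background subtraction and detrending. The header fields used do not say whether it was normalized between arrays. Its 75th percentile ranged from 372.3 to 653.1 over the arrays, so they did not share 1 scale. The deposited value table holds log2 values. Its columns share their quantiles, with column medians of 5.84 to 5.85. In 15 of 16 columns the spots rank as the logarithm of the mean spot signal does (Spearman correlation 0.999899 for medium control 3), and 4259 control spots are set to 0. Quantile normalization on the log2 scale without background subtraction would give such values, except for the departure in that column, which was not explained. This was read from the values, since no description of that step was given. Each array had 62976 spots, of which 58717 were not controls, for 42405 probes.

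Values were log2 of the processed signal, averaged over the spots of a probe, minus the array's 75th percentile of non-control probes. Probes were kept when well above background on every array of at least 1 group, which left 24600 probes. Probe names came from the files: 25715 probes were named through their RefSeq accession, 3627 of these with an updated symbol, and 16690 kept the name in the file. Each gene was represented by its probe with the highest mean, which gave 19629 genes. MDM2 and ZNF10, whose probes went in opposite directions, were not used as examples. Between 51.7% and 64.2% of the probes were well above background on an array, the 75th percentile of the signal was 372.3 to 653.1 intensity units, the median local background was 22 to 28, and 0 spots were saturated. The number of arrays per group limits the precision: the median standard error of an exposure minus DMSO was 0.219 on the log2 scale.

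All 16 arrays were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with the package data.table (version 1.17.8); figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Each exposure was compared with DMSO control, DMSO control with medium control, and FCCP with CCCP. Adjusted p-values are limma's moderated tests after Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. All tests were two-sided. Standard errors are those of the fitted contrasts. Gene lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the 35 lists of a comparison, and again with the correlation estimated from the arrays. Lists with at least 3 measured members were tested. Differences between exposures were tested as limma contrasts over all genes and as camera tests.

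The comparisons, lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule took, among genes past the threshold whose arrays in the compared groups did not overlap and whose name is a gene symbol, the 10 largest rises and 10 largest falls in each comparison, or 5 of each for FCCP minus CCCP and DMSO minus medium. It added up to 4 members past the threshold from each list and 17 fixed genes in every comparison. Where fewer than 5 genes passed, the 5 genes with the smallest p were taken. For readability not all of these genes are described, and some left out changed more than some described. Among those left out are RTP4, DACT3 and LIAT1 with CCCP, and HEYL, TYW2 and TRERF1 with FCCP. With dinoterb they include GOLGA6L1 and OR5M9, and with TCP KRTAP1-1, KLLN and C1GALT1C1L. Of the fixed genes, TXNIP, HMOX1, CDKN1A, HSPA1A, PPARGC1A and ALB are not described.

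Where a gene was not well above background in the dimmer group, the fold is a lower bound. It sets the mean of the brighter group over all its replicates against the mean of the dimmer group, taking on each array the higher of the probe's own signal and the lowest signal among probes well above background. No fold is given where the gene was below background in both groups.

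Arrays of equal replicate number were checked for pairing through the correlation of residuals from the group means across genes. In the 6 groups without benzo[a]pyrene, 31 of 31 pairs of equally numbered arrays had a correlation above 0.1 (0.132 to 0.606). After quantile normalization 30 of 31 did, the lowest at 0.008, and with normexp 31 of 31. In a group of 2 arrays the residuals mirror each other, so pairs between such groups give the same value for both numbers and the 31 are not separate checks. Benzo[a]pyrene arrays exceeded it with the other groups in 1 of 12 pairs (-0.195 to 0.105). A fit with replicate number as a block is therefore given beside each result it changes. Its value for benzo[a]pyrene assumes a pairing that the arrays of that group did not show. The 16 arrays lay on 2 slides of 8, and slide was read from the files. Replicate number and slide, each as the only block, were set in advance for the counts of genes and added after the data were seen for the gene lists and, for replicate number, for the intervals of FCCP minus CCCP. Each slide alone was added after the data were seen, as were the fits without arrays numbered 1, with both blocks, and with the replicate block without benzo[a]pyrene. Slide 1 held 1 DMSO, 2 medium and 1 TCP array, and slide 2 held 2 DMSO, 1 medium and 1 TCP array. Fits on 1 slide or without arrays numbered 1 thus leave 1 array in some groups. Calls lost or kept there are not replicated evidence.

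Correlations of changes between exposures share their DMSO arrays. The part due to the shared arrays was obtained from 100 simulations with each gene's own spread and independent arrays, which leave out the pairing by replicate number, and each correlation was repeated with medium controls for one of the exposures. Alternatives set in advance were quantile normalization with and without normexp background correction (offset 50), no filter or a stricter one on dim probes, all probes, the deposited table, eBayes with trend and robust options, only the compared groups in the fit, medium or pooled controls, and leaving out each array in turn.

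The fit was tested on simulated data with 200 changed genes of 19629 in each of 10 runs. Of the genes changed by 1 on the log2 scale, 48.9% were recovered for CCCP and 48.8% for benzo[a]pyrene. Of those changed by 2, 87.7% and 86% were recovered, and 5.27% and 5.4% of the calls were false. A list whose genes all rose by 1 on the log2 scale was called in 10 of 10 runs, with 0% of the other lists. That list was longer than any of the real lists, and most medians of the real lists were smaller. The 10 of 10 is therefore no measure of how often a real list would be called. Genes and arrays were independent in these simulations, without correlation between genes and without pairing by replicate number. The shares of false genes and lists therefore hold for that setting and do not carry over to the real arrays. The rule for material of a benzo[a]pyrene array on 1 TCP array was rewritten after the values were seen: 4 rules were tried, 2 argued against it and 2 left it open, and the last is used. Control spots and probes below background in every group were left out.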

Results

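Gene expression was measured in C3A cells, a human hepatoma-derived line with hepatocyte features, after 2 h with one of 5 chemicals. Benzo[a]pyrene is a polycyclic aromatic hydrocarbon that binds the aryl hydrocarbon receptor (AhR). CCCP and FCCP are carbonyl cyanide phenylhydrazones that carry protons across the inner mitochondrial membrane and so uncouple respiration from ATP synthesis. Dinoterb is a dinitrophenol herbicide, a class that also uncouples respiration. The labels do not say what TCP stands for and give no doses. Each chemical had 2 arrays, and DMSO and medium controls had 3 each, and this number limits the precision. Changes are given as log2 differences between group means ± SE of the limma fit, with n = 2 exposure arrays and n = 3 DMSO arrays unless stated otherwise.

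Replicate arrays correlated at 0.98 to 0.995 across genes. The 2 benzo[a]pyrene arrays were the most alike, at 0.9953, against 0.9797 to 0.9855 in the other exposures. The labels do not say whether they came from separate cultures, so n = 2 may overstate the replication of that exposure. The first principal component carried 35.2% of the variance and separated arrays by replicate number: in the 6 groups other than benzo[a]pyrene, arrays numbered 1 lay at 9.3 to 55.7 and the others at -36.5 to -0.2. Within a number it also separated exposures from controls. Exposures numbered 1 lay at 45.4 to 55.7 and controls numbered 1 at 9.3 and 12.4. Exposures numbered 2 lay at -10.1 to -0.2 and controls numbered 2 at -31.4 and -32.8. Arrays numbered 1 made up 1 of the 2 arrays of an exposure but 1 of the 3 DMSO arrays, so part of the difference by number enters the comparisons of CCCP, FCCP, dinoterb and TCP with DMSO. Both benzo[a]pyrene arrays lay with the arrays not numbered 1, at -36.6 and -36.7. In comparisons of benzo[a]pyrene the difference by number may therefore enter in the opposite direction. On arrays numbered 1 of these 6 groups the hypoxia list was higher by a median of 0.75 (adjusted p = 0.0998 with an estimated correlation) and the integrated stress response list by 0.41 (adjusted p = 0.121 with an estimated correlation). The cholesterol list stood at -1.13 (adjusted p = 0.0153 with an estimated correlation). Immediate early genes were higher on the control arrays numbered 1 (median 0.42, adjusted p = 8.75e-07, and adjusted p = 0.131 with an estimated correlation) and lower on the exposure arrays numbered 1 (-0.23, 0.0461, and adjusted p = 0.731 with an estimated correlation), so their change against DMSO differed between replicate numbers. Benzo[a]pyrene and CCCP were hybridized on slide 1 and dinoterb and FCCP on slide 2, while TCP, DMSO and medium arrays lay on both.

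**Figure D1:**
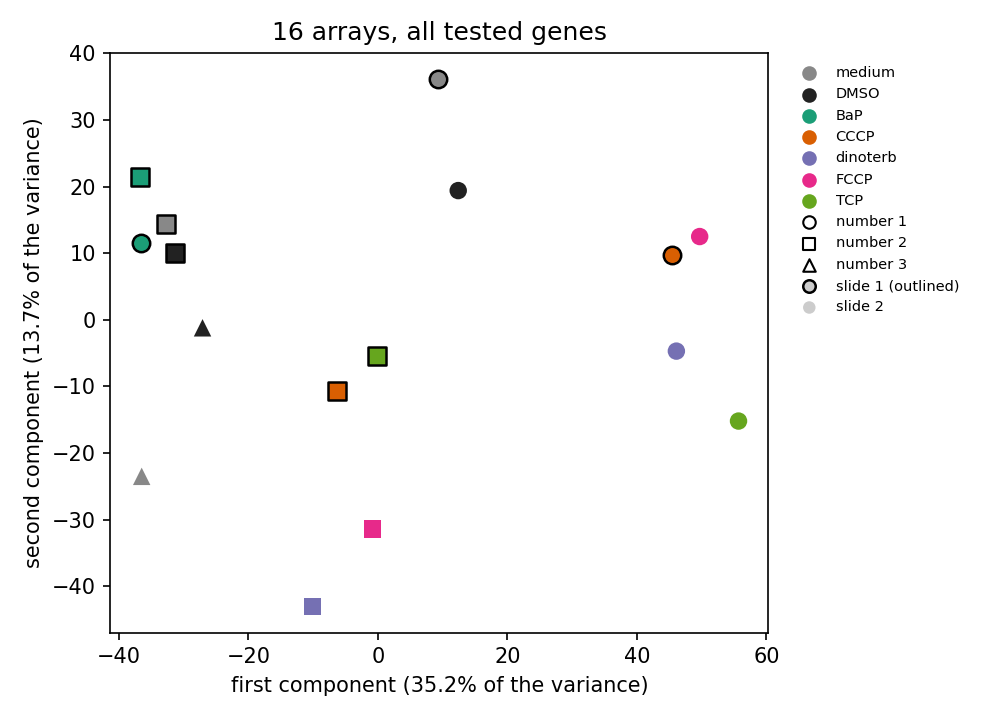
First against second principal component of log2 signal minus each array's 75th percentile, with axes in component units, 1 symbol per array, colour for the group, shape for the replicate number and an outline for slide 1. Arrays numbered 1 of the 6 groups other than benzo[a]pyrene lie at 9.3 to 55.7 on the first component, and both benzo[a]pyrene arrays lie at -36.6 and -36.7.

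The solvent was compared with medium to give the background of the exposure comparisons (n = 3 and n = 3). CYP1A1 differed by 0.07 ± 0.28. The genes with the smallest p were ALOX15, a lipoxygenase at least 1.98-fold lower with DMSO, where it was below background, and PNOC, which encodes the prepronociceptin peptide precursor, at 0.80 ± 0.18, each with adjusted p = 1. In the limma fit 0 of 19629 genes passed, with 252 at an unadjusted p under 0.05, and 0 passed with replicate number or slide as a block. Of the 35 lists 0 passed. Without DMSO replicate 1, 2 genes passed, and on slide 1 alone 7 did, against 0 on slide 2 alone. Lists were less stable: the hypoxia list passed with the replicate block (adjusted p = 0.0452), 4 lists passed without DMSO replicate 1, 4 without DMSO replicate 2, 1 without DMSO replicate 3, 7 without medium replicate 1, 4 without medium replicate 2 and 4 without medium replicate 3, and 6 and 5 passed on slides 1 and 2 alone.

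Benzo[a]pyrene minus DMSO asked which transcripts this AhR ligand changed within 2 h. CYP1A1, the monooxygenase gene most used as a marker of AhR activity, rose by 3.48 ± 0.31 (11.2-fold, adjusted p = 0.000785). CYP1B1, a related monooxygenase, rose too (adjusted p = 0.000544). It was below background on all 3 DMSO arrays and at least 9.68-fold higher. AHRR, the receptor's repressor, rose by 2.76 ± 0.42 (adjusted p = 0.0354), but did not pass with replicate number or slide as a block. It was well above background on 1 of 3 DMSO arrays. WNT11, a secreted Wnt ligand, rose by 2.95 ± 0.35 (7.72-fold, adjusted p = 0.00652). GSTP1, a glutathione transferase, rose by 2.43 ± 0.33 (5.4-fold, adjusted p = 0.0173). TIPARP, an ADP-ribosyltransferase that restrains the receptor, was 0.83 ± 0.14 higher and did not pass (adjusted p = 0.0711, and 0.048 with replicate number as a block).

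Of 14 measured AhR targets 3 rose and 0 fell, 11 did not pass, and 7 rose when adjusted over the list alone. The list shifted upwards with a median of 0.64 (adjusted p = 8.84e-11). This call held with an estimated correlation (adjusted p = 0.0147), with replicate number as a block (1.39e-05) and with slide as a block (3.74e-11). On slide 1 alone, with 1 DMSO array, the list shifted in the same direction. RADIL (2.89 ± 0.26), NKAIN1 (2.33 ± 0.24), RGMB (1.56 ± 0.17) and SPRED1, an inhibitor of Ras signalling (1.55 ± 0.13), rose too. FRMD4B was the gene that fell, by 1.52 ± 0.23, and was well above background on 1 of the 2 benzo[a]pyrene arrays.

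Another 8 lists passed with small medians, and 0 of their members passed alone. They were cholesterol biosynthesis upwards (median 0.31, 24 members, adjusted p = 0.0272), and downwards hypoxia targets (-0.37, 0.00396), bile acid genes (-0.35, 0.0217), the circadian clock (-0.21, 0.0217), ribosomal proteins (-0.16, 3.75e-05), hepatocyte secretory markers (-0.11, 0.0197) and nuclear genes of respiratory complex I (-0.08, 0.00879) and complexes II to V (-0.10, 0.0058). With an estimated correlation bile acid genes had adjusted p = 0.298 and the other 7 lists adjusted p = 0.912. On slide 1, where both benzo[a]pyrene arrays lay, AhR targets were the 1 list that passed, and slide as a block ended the calls of complex I (0.603), complexes II to V (0.326), cholesterol (0.675), secretory markers (0.452) and ribosomal proteins (0.326). Without the arrays numbered 1, which differed in hypoxia and cholesterol genes, hypoxia targets had adjusted p = 0.0916, cholesterol genes turned lower (0.48), and the other 6 lists had adjusted p of 0.0696 to 0.256. The calls of complex I, complexes II to V, ribosomal proteins and secretory markers also ended with quantile normalization (0.468, 0.444, 0.176 and 0.83), as did the first 3 with normexp (0.426, 0.344 and 0.126). Medium controls ended those of complex I (0.108) and complexes II to V (0.0975), and keeping dim probes those of complex I (0.106), complexes II to V (0.0818), secretory markers (0.106), bile acid genes (0.0663) and the clock (0.0818). The secretory markers turned upwards with normexp and quantile normalization (adjusted p = 0.955). Cholesterol genes turned downwards on slide 1 alone (adjusted p = 0.832) and without DMSO replicate 1 (0.97). Without benzo[a]pyrene replicate 1, complex I had adjusted p = 0.0795, complexes II to V 0.0513, cholesterol 0.0795, bile acid genes 0.073, secretory markers 0.21 and the clock 0.073. Hypoxia targets (0.297), bile acid genes (0.0621), secretory markers (0.0741) and the clock (0.102) also lost their call without DMSO replicate 1, and secretory markers did without DMSO replicate 3 (0.0686).

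In all, 21 genes passed for benzo[a]pyrene, 20 higher and 1 lower, and 18 changed at least 2-fold. The replicate block gave 25 genes, with 20 of the 21 kept and AHRR lost (adjusted p = 0.106). With slide as a block 21 passed, with 17 kept and AHRR lost (0.137). On slide 1 alone, with 1 DMSO array, the change of CYP1A1 was 3.17. The count was 6 without benzo[a]pyrene replicate 1, 8 without benzo[a]pyrene replicate 2, 12 without DMSO replicate 1 and 10 without DMSO replicate 3. Of 11 named genes that passed, 4, 4, 7 and 8 did so without these arrays and 8 without DMSO replicate 2, and CYP1A1, CYP1B1, RADIL and SPRED1 did whichever array was left out. Normexp with quantile normalization gave 37 genes and 34 passed in the deposited table.

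CCCP minus DMSO asked which transcripts this uncoupler changed. FOS, a subunit of the AP-1 transcription factor, rose by 3.50 ± 0.73 (11.3-fold, adjusted p = 0.0442), but did not pass with the replicate block (0.0617) or with slide as a block (0.11). CCN1, a matricellular signalling protein, rose by 2.91 ± 0.54 (7.51-fold, adjusted p = 0.0269) and DUSP1, a phosphatase that switches off MAP kinases, by 2.66 ± 0.48 (6.31-fold, adjusted p = 0.0249). PFKFB3, whose product makes the main allosteric activator of glycolysis, rose by 2.67 ± 0.23 (6.37-fold, adjusted p = 0.000931). PCK1, the cytosolic enzyme of gluconeogenesis, rose by 1.74 ± 0.27 (3.34-fold, adjusted p = 0.0147), and FOXO1, a transcription factor that drives PCK1, by 1.50 ± 0.14 (adjusted p = 0.0018). CYP1A1 fell by 2.20 ± 0.31 (adjusted p = 0.00873).

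Of 31 immediate early genes 8 rose and 0 fell (17 rose when adjusted over the list alone, 11 with the replicate block), with a median of 1.46 (adjusted p = 2.76e-20, and 0.0363 with an estimated correlation). Of 14 NF-kappaB and inflammatory genes 2 rose, CCL20, a chemokine (1.11 ± 0.17), and BIRC3, an inhibitor of apoptosis (0.95 ± 0.20), and 7 rose adjusted over the list alone (median 0.73, adjusted p = 1.11e-06, and 0.0363 with an estimated correlation). Of 22 ribosome biogenesis genes 1 fell, RRS1, by 0.99 ± 0.15, and 5 fell adjusted over the list alone (median -0.25, adjusted p = 4.76e-05, and 0.0258 with an estimated correlation). On slide 1 alone, with 2 CCCP arrays against 1 DMSO array, these lists shifted in the same directions.

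Of 25 hypoxia targets PFKFB3 rose, 6 rose adjusted over the list alone and 5 with the replicate block (median 0.72, adjusted p = 8.87e-07). The hypoxia list also lay higher on slide 1 alone, with 1 DMSO array, and without the arrays numbered 1, where this list was high, with 1 CCCP array left. Its call had adjusted p = 0.728 with an estimated correlation. Nuclear genes of complex I (38 members, median -0.19, adjusted p = 0.000364) and of complexes II to V (40 members, -0.17, 0.00635) shifted downwards with 0 members past the threshold, and both had adjusted p = 0.728 with an estimated correlation. Their calls ended on slide 1 alone (0.076 and 0.207) and with slide as a block (0.0862 and 0.239), and that of complexes II to V ended without CCCP replicate 2 (0.196), with medium controls (0.129), with quantile normalization (0.124) and with normexp (0.0876). Glucose-sensing MondoA/ChREBP targets (10 members) had a median of -0.40 (adjusted p = 0.0488), with 4 lower and 1 higher adjusted over the list alone. Adjusted p = 0.214 with an estimated correlation, 0.0704 with medium controls, 0.21 without CCCP replicate 1, 0.0546 without DMSO replicate 1, 0.103 without the arrays numbered 1, 0.063 with dim probes kept and 0.076 on slide 1 alone ended this call.

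Other genes with large rises were RASD1, a Ras-like GTPase (2.99 ± 0.51), GADD45B, a stress-induced regulator of growth arrest (2.46 ± 0.38), ELF3 (2.33 ± 0.42), PIM1, a survival kinase (2.23 ± 0.25), ZFP36, which destabilizes AU-rich messages (2.22 ± 0.36), and PPP1R15A, which directs the dephosphorylation of eIF2alpha (1.83 ± 0.27). EIF5, a translation initiation factor, fell by 1.82 ± 0.21, NFYA, a CCAAT-binding factor, by 1.65 ± 0.22, and ABCD3, a peroxisomal transporter, by 1.59 ± 0.20. DDIT3 (1.74 ± 0.48, adjusted p = 0.116) and ATF3 (1.68 ± 0.40, 0.0746), transcription factors of the stress response, did not pass, but did with replicate number as a block (0.0282 and 0.0163). EGR1 was 2.88 ± 0.89 higher and did not pass (adjusted p = 0.162).

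With CCCP, 285 genes passed, 153 higher and 132 lower, and 114 changed at least 2-fold. The replicate block gave 683 genes, with 278 kept, but FOS did not pass in it (adjusted p = 0.0617). The rise of FOS was 4.39 without CCCP replicate 1 and 2.61 without CCCP replicate 2, both against all DMSO arrays. Against the DMSO array of equal number, FOS rose by 1.44 for number 1 and 4.97 for number 2. In the same order CCN1 rose by 1.56 and 3.69, RASD1 by 1.68 and 3.88 and DUSP1 by 1.81 and 3.06. EGR1 rose by 1.26 and 4.27, whereas PFKFB3 rose by 2.83 and 2.27. Slide as a block gave 112, with 98 kept, and ended the calls of FOS (0.11), RASD1 (0.0571), CCN1 (0.0833), DUSP1 (0.0571), ELF3 (0.0838) and BIRC3 (0.0684). On slide 1 alone, with 1 DMSO array, the change of CYP1A1 was -2.51. The count was 40 without CCCP replicate 1, 26 without CCCP replicate 2, 111 without DMSO replicate 1, 60 without DMSO replicate 2 and 41 without DMSO replicate 3. Of 32 named genes that passed, 8, 5, 22, 8 and 8 did so without these arrays in turn, and EIF5, FOXO1, PFKFB3 and PIM1 did whichever array was left out. CYP1A1 did not pass without CCCP replicate 2 (fell by 1.97, adjusted p = 0.0769) or with both blocks (2.16, 0.0516).

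FCCP minus DMSO asked the same of the second carbonyl cyanide phenylhydrazone. ZFP36 rose by 2.61 ± 0.36 (adjusted p = 0.00892), CCN1 by 2.61 ± 0.54 (0.0401) and DUSP1 by 2.59 ± 0.48 (0.0266). Against the DMSO array of equal number, CCN1 rose by 1.27 for number 1 and 3.38 for number 2. DUSP1 rose by 1.57 and 3.16 and ZFP36 by 1.88 and 3.11 in that order. PFKFB3 rose by 2.45 ± 0.23 (5.45-fold, adjusted p = 0.00139), PCK1 by 1.93 ± 0.27 (0.00904) and FOXO1 by 1.27 ± 0.14 (0.00304). CYP1A1 fell by 1.95 ± 0.31 (adjusted p = 0.0157), and HSPA8, the constitutive cytosolic HSP70 chaperone, by 0.98 ± 0.14 (0.0118). GRIP2, a scaffold protein of synapses, was at least 4.46-fold higher (adjusted p = 0.00904), but when dim probes were kept another of its probes was taken, and its change was -0.07. The call of GRIP2 also ended without FCCP replicate 1 (0.0536).

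Of 31 immediate early genes 7 rose and 0 fell (16 rose adjusted over the list alone, 11 with the replicate block), with a median of 1.24 (adjusted p = 3.73e-19, and 0.0432 with an estimated correlation). FOS was 3.27 ± 0.73 higher and did not pass (0.0516). Of 14 NF-kappaB genes 2 rose, and 6 did adjusted over the list alone (median 0.63, adjusted p = 6.66e-07, and 0.0342 with an estimated correlation). Of 22 ribosome biogenesis genes 3 fell, RRS1 by 0.85 ± 0.15, the nucleolar methyltransferase NOP2 by 0.56 ± 0.12 and the RNA polymerase I subunit POLR1B by 0.47 ± 0.10, and 5 fell adjusted over the list alone (median -0.25, adjusted p = 0.000539, and 0.0342 with an estimated correlation). On slide 2 alone these lists kept their calls (1.96e-17, 1.25e-06 and 0.00599).

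Among 25 hypoxia targets PFKFB3 rose, with 4 higher adjusted over the list alone and 6 with the replicate block (median 0.69, adjusted p = 1.62e-07). That call held on slide 2 alone (3.34e-06), and had adjusted p = 0.707 with an estimated correlation. Without the arrays numbered 1, which leaves 1 FCCP array, the list still lay higher. Of 31 KRAB zinc finger genes, a family with short-lived messages, ZNF30 (fell by 0.87) and ZNF45 (fell by 0.74) passed, with a list median of -0.21 (adjusted p = 0.0195, and adjusted p = 0.707 with an estimated correlation). This call ended with medium controls (0.148), without FCCP replicate 1 (0.739), without the arrays numbered 1 (0.857) and on slide 2 alone (0.0563). RASD1 (2.71 ± 0.51), PIM1 (2.36 ± 0.25), GADD45B (2.27 ± 0.38), KLF6, a zinc finger factor (1.70 ± 0.35), and GDF15, a stress-induced cytokine (1.15 ± 0.23), rose as well, though the change of KLF6 was 2.36 without FCCP replicate 1 and 1.04 without FCCP replicate 2 (adjusted p = 0.141). EIF5 fell by 1.86 ± 0.21. ATF3 was 1.51 ± 0.40 higher and passed with the replicate block (adjusted p = 0.104, and 0.023 in the block).

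With FCCP, 317 genes passed, 151 higher and 166 lower, and 131 changed at least 2-fold. This balance depended on the setting. More genes were higher than lower with quantile normalization (169 and 128), with normexp (247 and 166), in the deposited table (211 and 147), without a filter (29 and 11), with the stricter filter (186 and 169), with trend and robust eBayes (186 and 177), with the replicate block (400 and 395), with both blocks (27 and 11) and without each array of these groups other than FCCP replicate 2. The replicate block gave 795 genes, with 311 kept and NR0B2, a nuclear receptor corepressor, lost (adjusted p = 0.0503). Slide as a block gave 170, with 165 kept, and ended the calls of RASD1 (0.0579), CCN1 (0.0725), DUSP1 (0.0555), ELF3 (0.0655), KLF6 (0.0802), GDF15 (0.0634), NOP2 (0.0793) and POLR1B (0.074), while 0 genes passed on slide 2 alone (CYP1A1 -1.79, adjusted p = 0.6). The count was 112 without FCCP replicate 1, 117 without DMSO replicate 1, 48 without DMSO replicate 2 and 52 without DMSO replicate 3. Of 35 named genes that passed, 10, 22, 10 and 9 did so without these arrays and 21 without FCCP replicate 2, and EIF5, FOXO1, MAFG, PCK1, PFKFB3, PIM1 and ZFP36 did whichever array was left out. CYP1A1 did not pass without FCCP replicate 1 (fell by 1.93, adjusted p = 0.0797), DMSO replicate 2 (1.79, 0.0659) or DMSO replicate 3 (1.88, 0.065), nor with dim probes kept (fell by 1.95, adjusted p = 0.0526) or with both blocks (1.89, 0.125).

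FCCP minus CCCP compared analogs that differ in their ring substituent, trifluoromethoxy in FCCP and chlorine in CCCP (n = 2 and n = 2, doses not given). Intervals included 0 for the following response genes. The difference was -0.23 for PFKFB3 (95% interval -0.78 to 0.33), 0.25 for CYP1A1 (-0.48 to 0.99), -0.23 for FOXO1 (-0.58 to 0.11), 0.14 for RRS1 (-0.22 to 0.50) and -0.05 for EIF5 (-0.55 to 0.46). The intervals were wide for FOS (-0.23, -1.98 to 1.53) and DUSP1 (-0.07, -1.21 to 1.07). With the replicate block they were -2.09 to 1.64 for FOS, -0.93 to 0.78 for DUSP1, -0.69 to 0.24 for PFKFB3, -0.56 to 1.07 for CYP1A1, -0.49 to 0.03 for FOXO1, -0.16 to 0.44 for RRS1 and -0.58 to 0.49 for EIF5. Of the 410 genes that passed in either exposure, 344 had an interval within 1 of 0 on the log2 scale and 55 had an interval that excluded 0. Among them the median size of the difference was 0.133 and the median half-width of the interval 0.393, and 4 differed, or 14 adjusted over these genes alone. With the block 349 had an interval within 1 of 0 and 65 one that excluded 0, the median half-width was 0.339, and 2 differed, or 16 adjusted over these genes alone. The 192 genes that passed in both were chosen by agreement and do not show that the compounds act alike.

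In FCCP minus CCCP 4 features passed, each higher with FCCP and below background with CCCP, and 592 genes had an unadjusted p under 0.05. GRIP2 was at least 6.19-fold higher (adjusted p = 0.0383). The others were an unnamed transcript and a pair of long intergenic RNAs on chromosomes 11 and 7. They were at least 7.42-fold, 6.89-fold and 6.25-fold higher. The replicate block kept the 2 intergenic RNAs and gave adjusted p = 0.0979 for GRIP2. FCCP arrays lay on slide 2 and CCCP arrays on slide 1, so neither slide gives a value for this difference. Slide as a block, estimated through the groups on both slides, kept the chromosome 11 RNA (0.00199) and ended the calls of GRIP2 (0.517) and the chromosome 7 RNA (0.0742). The count was 18 without FCCP replicate 1, 10 without FCCP replicate 2 and 2 without CCCP replicate 2, and of the 4 features the chromosome 11 RNA passed whichever array was left out. With normexp, with the stricter filter and with trend and robust eBayes 0 passed, and 2 did in the deposited table. When dim probes were kept, the probe then taken for GRIP2 differed by -0.02.

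Of the lists, that of the metallothioneins (9 measured) shifted upwards with FCCP against CCCP (median 0.56, adjusted p = 2.43e-05). No member was among the features that passed alone. The call had adjusted p = 0.99 with an estimated correlation and 0.005 with slide as a block. Complex I (0.14, adjusted p = 2.12e-06), complexes II to V (0.13, 0.000341), secretory markers (0.13, 0.00179) and ribosomal proteins (0.15, 0.000163) were also higher, each with adjusted p = 0.99 with an estimated correlation. With slide as a block these had adjusted p = 0.521, 0.762, 0.667 and 0.594, and ribosomal proteins turned lower. The calls of complexes II to V, secretory markers and ribosomal proteins ended without CCCP replicate 2 (0.158, 0.555 and 0.729, the last turned lower) and without FCCP replicate 1 (0.0816, 0.542 and 0.403). The same 3 ended with quantile normalization (0.401, 0.967 and 0.967) and with normexp (0.496, 0.866 and 0.989), and that of secretory markers without the arrays numbered 1 (0.123). Keeping dim probes ended all 5, metallothioneins with adjusted p = 0.0503, complex I 0.167, complexes II to V 0.47, secretory markers 0.457 and ribosomal proteins 0.352.

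Dinoterb minus DMSO asked which transcripts the dinitrophenol changed. DDIT3, a transcription factor of the integrated stress response, rose by 2.86 ± 0.48 (7.25-fold, adjusted p = 0.0186). ATF3, induced in the same response, rose by 2.74 ± 0.40 (6.66-fold, 0.0122), and PPP1R15A by 2.16 ± 0.27 (4.48-fold, 0.00649). GDF15 rose by 1.27 ± 0.23 (0.0273), PFKFB3 by 1.23 ± 0.23 (0.0305) and PCK1 by 1.62 ± 0.27 (0.018). CYP1A1 was at -0.91 ± 0.31 and did not pass (0.191). NDUFB3, a subunit of respiratory complex I, fell by 0.76 ± 0.13 (0.0182), and FJX1 was at least 3.86-fold lower (0.00649).

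Of 34 genes of the ATF4 and integrated stress response 4 rose and 0 fell (15 rose adjusted over the list alone, 14 with the replicate block), with a median of 0.73 (adjusted p = 4.89e-10, and adjusted p = 0.313 with an estimated correlation). CHAC1, which degrades glutathione (3.67 ± 0.93, adjusted p = 0.0857), and the pseudokinase TRIB3 (0.74 ± 0.21, 0.119) did not pass, but did with replicate number as a block (0.0236 and 0.0336). Without the arrays numbered 1, where this list was high, it still lay higher, with 1 dinoterb array left. Of 31 immediate early genes 7 rose (16 adjusted over the list alone, 9 with the block), including CCN1 (2.53 ± 0.54), DUSP1 (2.52 ± 0.48) and ID1, an inhibitor of helix-loop-helix factors (1.51 ± 0.24), with a median of 1.26 (adjusted p = 3.52e-15, and adjusted p = 0.0839 with an estimated correlation). Among 14 NF-kappaB genes 0 passed and 2 rose adjusted over the list alone (median 0.61, adjusted p = 7.34e-06, and adjusted p = 0.0839 with an estimated correlation). Of 22 ribosome biogenesis genes RRS1 fell by 0.77 ± 0.15 (2 fell adjusted over the list alone; median -0.24, adjusted p = 0.00643, and adjusted p = 0.0839 with an estimated correlation). These 4 lists kept their calls on slide 2 alone (2.5e-09, 2.75e-13, 1.33e-05 and 0.0284).

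The respiratory chain lists shifted downwards with dinoterb, complex I with a median of -0.24 (adjusted p = 4.33e-08; 3 fell adjusted over the list alone) and complexes II to V with -0.21 (2.27e-06), each with adjusted p = 0.395 with an estimated correlation. Both held on slide 2 alone (4.95e-08 and 1.2e-07). Hypoxia targets (median 0.18, adjusted p = 0.0497) and the circadian clock (0.18, 0.0439) also passed, with adjusted p = 0.789 and 0.51 with an estimated correlation. NR1D1, a clock repressor, rose by 1.13 ± 0.19. The replicate block ended both calls (0.105 and 0.0577), as did slide 2 alone (0.178 and 0.125) and leaving out dinoterb replicate 1 (0.997 and 0.53), DMSO replicate 2 (0.172 and 0.0883) or DMSO replicate 3 (0.176 and 0.0645), and keeping dim probes (0.158 each). Slide as a block ended that of the hypoxia list (0.0724), and leaving out the arrays numbered 1 that of the clock (0.105).

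MITF, a transcription factor of the lysosome-regulating family, was at least 2.23-fold higher (adjusted p = 0.000609), and TBX15 rose by 2.44 ± 0.50 and RASD1 by 2.48 ± 0.51. MAFG, a partner of NRF2, rose by 1.21 ± 0.13 and FOXO1 by 1.09 ± 0.14. GEMIN6, which assembles spliceosomal particles, fell by 1.01 ± 0.13, and KBTBD6 and FAM217B each fell by 1.13.

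With dinoterb, 242 genes passed, 178 higher and 64 lower, and 97 changed at least 2-fold. The replicate block gave 855 genes, with 242 kept. Normexp with quantile normalization gave 548, quantile normalization alone 398, and 446 passed in the deposited table. Slide as a block gave 195, with 174 kept, and ended the calls of CCN1 (adjusted p = 0.0823), DUSP1 (0.0574), RASD1 (0.0785) and TBX15 (0.0758), while 0 genes passed on slide 2 alone. The count was 4 without dinoterb replicate 1, 56 without dinoterb replicate 2, 106 without DMSO replicate 1, 42 without DMSO replicate 2 and 37 without DMSO replicate 3. Of 31 named genes that passed, 1, 9, 19, 8 and 9 did so without these arrays in turn, and MITF was the one that did whichever array was left out.

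TCP minus DMSO asked which transcripts this chemical changed. CYP1A1 rose by 2.48 ± 0.31 (5.59-fold, adjusted p = 0.00241) and TIPARP by 2.28 ± 0.14 (4.86-fold, 6.67e-05), while CYP1B1 was at least 11-fold higher (8.99e-05). ATF3 rose by 3.33 ± 0.40 (10-fold, adjusted p = 0.00218), PPP1R15A by 3.21 ± 0.27 (9.28-fold, 0.000278) and DDIT3 by 2.83 ± 0.48 (7.12-fold, 0.0103). RRS1 fell by 1.17 ± 0.15 (0.00295) and NDUFB3 by 0.71 ± 0.13 (0.0133). AHRR was well above background on 0 of 2 TCP and 1 of 3 DMSO arrays, too dim to compare.

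Of 14 AhR targets 3 rose and 0 fell (5 rose and 1 fell adjusted over the list alone), with a median of 0.61 (adjusted p = 1.76e-05, and 0.0443 with an estimated correlation). Of 31 immediate early genes 10 rose (21 adjusted over the list alone, 12 with the replicate block), among them CCN1 (3.04 ± 0.54), DUSP1 (2.91 ± 0.48) and KLF6 (2.35 ± 0.35), with a median of 1.52 (adjusted p = 7.29e-19, and 0.0443 with an estimated correlation). Of 14 NF-kappaB genes 4 rose (8 adjusted over the list alone), including CXCL1, a chemokine at least 3.61-fold higher, BIRC3 (1.33 ± 0.20) and the pathway's inhibitor NFKBIA (1.08 ± 0.24), with a median of 0.92 (adjusted p = 1.24e-08, and 0.0297 with an estimated correlation). CXCL1 did not pass without TCP replicate 1 (0.309). Of 22 ribosome biogenesis genes RRS1 and PNO1 fell (6 adjusted over the list alone; median -0.23, adjusted p = 0.00104, and 0.0443 with an estimated correlation). On slides 1 and 2 alone these lists shifted in the same directions. Each slide holds 1 TCP array, with 1 DMSO array on slide 1 and 2 on slide 2, so this is no replicated check.

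Of 34 integrated stress response genes 5 rose with TCP (10 adjusted over the list alone, 14 with the replicate block; median 0.64, adjusted p = 1.66e-08, and adjusted p = 0.361 with an estimated correlation). CHAC1 (3.26 ± 0.93, adjusted p = 0.0879) and DDIT4, an inhibitor of mTORC1 (2.67 ± 0.82, 0.11), did not pass, but did with the block (0.024 and 0.044). Without the arrays numbered 1 the list still lay higher, with 1 TCP array left. Hypoxia targets had a median of 0.26 (PFKFB3 rose, 5 with the block; adjusted p = 0.00289, and adjusted p = 0.861 with an estimated correlation), a call that ended without TCP replicate 1 (0.257). Complex I (median -0.20, adjusted p = 3.89e-05; NDUFB3 and NDUFC2 fell) and complexes II to V (-0.20, 0.00104) had adjusted p = 0.6 with an estimated correlation. Both calls ended without TCP replicate 2 (0.0727 and 0.24), and that of complexes II to V ended on slide 2 alone (0.121). Autophagy and lysosome targets (median 0.12, adjusted p = 0.0308; UVRAG rose by 0.87 ± 0.17) had adjusted p = 0.6 with an estimated correlation, 0.209 without TCP replicate 1, 0.058 without DMSO replicate 2, 0.0549 without the arrays numbered 1 and 0.058 on slide 1 alone.

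GADD45B (2.96 ± 0.38), the small MAF factor MAFF (2.79 ± 0.48), HES1, a Notch target (2.62 ± 0.44), PCK1 (2.10 ± 0.27), PFKFB3 (1.78 ± 0.23) and GDF15 (1.77 ± 0.23) rose as well. The change of HES1 was 3.28 without TCP replicate 1 and 1.96 without TCP replicate 2 (adjusted p = 0.0543). FZD1, a Wnt receptor, was at least 4.15-fold lower and FJX1 at least 3.53-fold lower. RIMBP3 fell by 3.59 ± 0.52 and was well above background on 1 of 2 TCP arrays (a change of -2.40 without TCP replicate 1 and -4.77 without TCP replicate 2). ND6, a complex I subunit encoded in mitochondrial DNA, fell by 1.60 ± 0.38 (adjusted p = 0.044, and 0.0605 with slide as a block), the mitochondrial chaperonin HSPE1 by 0.65 ± 0.14, and SPP1, which encodes osteopontin, by 0.65 ± 0.11.

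With TCP, 672 genes passed, 344 higher and 328 lower, and 266 changed at least 2-fold. The replicate block gave 1501 genes, with 661 kept. With slide as a block there were 732, with 624 kept, and each slide alone gave 2. CYP1A1 rose by 1.80 on slide 1 alone (1 TCP and 1 DMSO array) and by 3.01 on slide 2 alone (1 TCP and 2 DMSO arrays). The count was 86 without TCP replicate 1, 361 without DMSO replicate 1, 259 without DMSO replicate 2 and 215 without DMSO replicate 3. Of 46 named genes that passed, 15, 30, 28 and 24 did so without these arrays and 36 without TCP replicate 2, and 13 did whichever array was left out, among them ATF3, CYP1A1, CYP1B1, PPP1R15A, RRS1 and TIPARP.

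**Figure D2:**
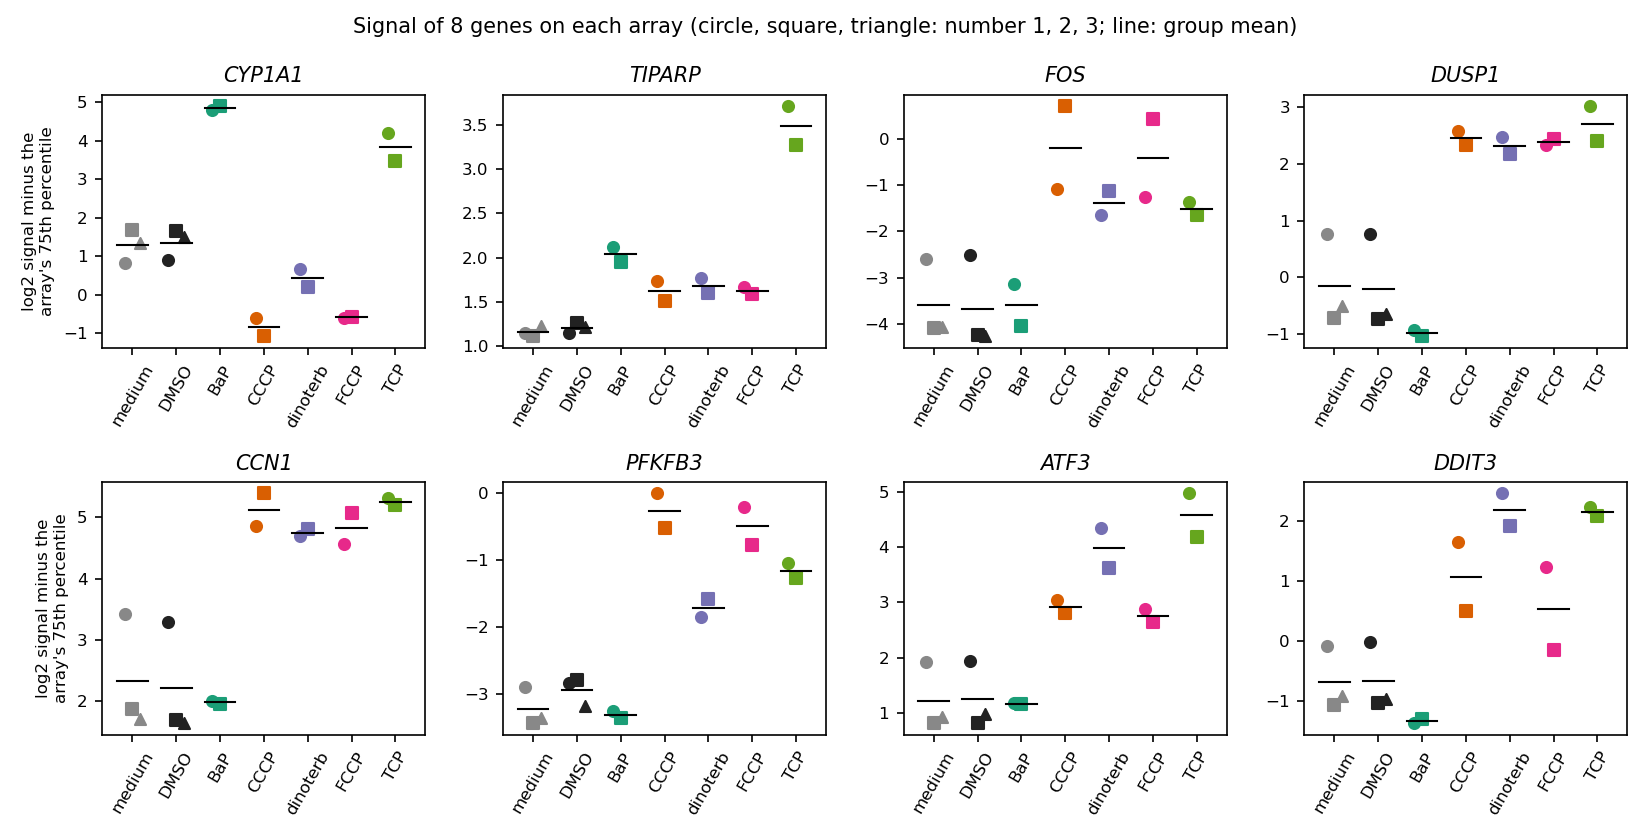
Log2 signal minus the array's 75th percentile of 8 genes in the 7 groups, with 1 symbol per array (circle, square and triangle for replicates 1, 2 and 3) and a line at each group mean. CYP1A1 lies at 4.79 and 4.89 with benzo[a]pyrene, 4.21 and 3.47 with TCP, 0.91 to 1.67 with DMSO, and -1.07 to -0.57 with CCCP and FCCP.

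Differences between exposures were tested directly. CYP1A1 was lower with CCCP than with TCP (difference -4.68 ± 0.34, adjusted p = 0.000185) and with FCCP than with TCP (-4.43, 0.000518), and so was TIPARP (-1.87 ± 0.15, 0.0005, and -1.86, 0.000518). Benzo[a]pyrene and TCP did not differ past the threshold in CYP1A1 (1.00 ± 0.34, adjusted p = 0.127) or CYP1B1 (-0.18 ± 0.35, 0.804), whereas TIPARP was lower with benzo[a]pyrene (-1.45 ± 0.15, 0.00217) and AHRR was well above background on 2 of 2 benzo[a]pyrene arrays and 0 of 2 TCP arrays (0.00884). DDIT3 was lower with benzo[a]pyrene than with TCP (-3.50 ± 0.53, 0.00697). CCCP and dinoterb did not differ past the threshold in DDIT3 (-1.12, adjusted p = 0.784), ATF3 (-1.06, 0.689) or PFKFB3 (1.45 ± 0.25, 0.128), nor did FCCP and dinoterb in DDIT3 (-1.65, 0.353) or ATF3 (-1.23, 0.468). PFKFB3 was 1.22 ± 0.25 higher with FCCP than with dinoterb (0.105), which passed with the replicate block (0.045).

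As a list, integrated stress response genes lay lower with CCCP than with dinoterb (median difference -0.44, adjusted p = 5.42e-09) and TCP (-0.52, 5.74e-12), and with FCCP than with dinoterb (-0.48, 7.74e-10) and TCP (-0.51, 2.48e-11). In that order adjusted p = 0.684, 0.336, 0.408 and 0.304 with an estimated correlation. AhR targets lay lower with CCCP than with TCP (-0.40, 3.01e-10), with FCCP than with TCP (-0.55, 3.08e-10) and with dinoterb than with TCP (-0.48, 9.94e-11), and these calls held with an estimated correlation (0.0194, 0.0195 and 0.0149). CCCP minus dinoterb gave 0 genes higher and 2 lower (3 and 15 with the replicate block), CCCP minus TCP 0 and 6 (3 and 8), FCCP minus dinoterb 4 and 18 (19 and 98), FCCP minus TCP 12 and 23 (27 and 65) and dinoterb minus TCP 1 and 5 (1 and 6). Benzo[a]pyrene minus TCP gave 296 and 415 (1736 and 1519 with the block, which assumes that benzo[a]pyrene is paired). These counts may hold part of the difference by number, since no benzo[a]pyrene array lay with the arrays numbered 1.

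Counts of shared genes do not allow for the shared DMSO arrays or for pairing by replicate number, and independent calls are no measure of either. CCCP and FCCP had 111 genes higher and 81 lower in common, where independent calls would give 1.18 and 1.12, and with medium arrays as the control of one of them 106 to 114 higher and 80 to 90 lower were shared. In all 4 exposures 57 genes rose, among them CCN1, DUSP1, FOXO1, GADD45B, JUNB, PCK1, PFKFB3, PIM1 and PPP1R15A, and 13 fell, among them RRS1 and PLAT, which encodes tissue plasminogen activator, all against the same DMSO arrays. Benzo[a]pyrene and TCP shared 10 genes that rose and 0 that fell (7 or 11 higher with medium controls for one of them), including CYP1A1, CYP1B1, RADIL, RGMB, SPRED1, TBX3 and SOCS2, a suppressor of cytokine signalling.

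Across genes, which are not independent replicates, the changes of CCCP and FCCP correlated at 0.691, CCCP and TCP at 0.687, dinoterb and TCP at 0.663, FCCP and TCP at 0.645, CCCP and dinoterb at 0.607 and FCCP and dinoterb at 0.548. Shared DMSO arrays alone gave 0.401 in simulations of independent arrays (0.371 to 0.426). These left out the pairing by replicate number, which also makes the changes of the 4 exposures correlate, so the value without a common response is not known. With medium controls for the first exposure CCCP and FCCP correlated at 0.615, and for the second at 0.517. The changes of benzo[a]pyrene correlated at -0.067 to 0.131 with the others, below the simulated value. Both benzo[a]pyrene arrays lay with the arrays not numbered 1 on the first component, which can lower these correlations. They are thus no measure of how unlike the responses were. The 3 DMSO arrays cannot be split with at least 2 in each part, so some of each correlation may come from shared controls.

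**Figure D3:**
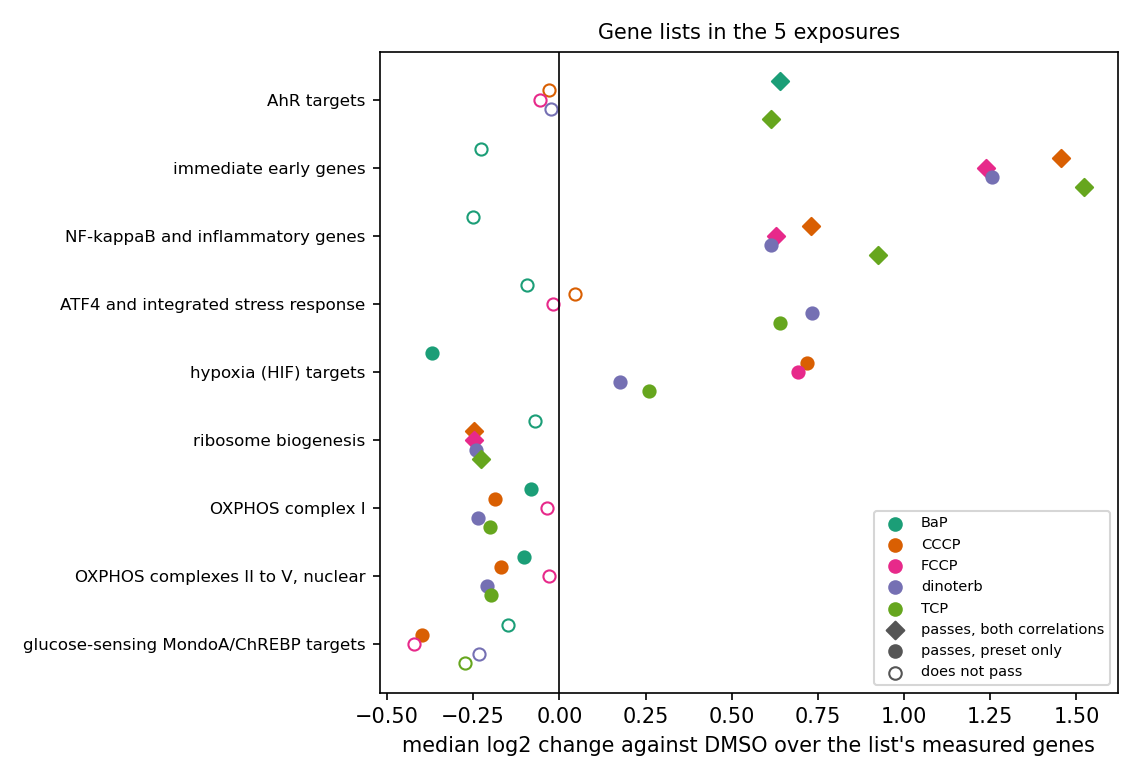
Median log2 change against DMSO of 9 gene lists in the 5 exposures, with a diamond where the list passed with both correlations, a filled circle where it passed with the preset correlation alone and an open circle where it did not pass. Immediate early genes have medians of 1.24 to 1.52 in the 4 exposures other than benzo[a]pyrene, and AhR targets pass with benzo[a]pyrene (0.64) and TCP (0.61).

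Of the 35 lists, 18 did not pass in any of the 7 comparisons. Their smallest adjusted p was 0.0639 for p53 targets and for S phase genes, 0.0649 for the unfolded protein response of the endoplasmic reticulum, 0.0791 for mitochondrial chaperones and proteases, 0.0921 for the cytosolic heat shock response, 0.134 for gluconeogenesis, 0.135 for glycolysis, 0.157 for mitochondrial DNA-encoded messages, 0.174 for fatty acid synthesis, 0.216 for fatty acid oxidation and for hepatocyte transcription factors, 0.235 for mitochondrial biogenesis, 0.312 for G2/M genes, 0.315 for NRF2 targets and 0.65 for CAR and PXR targets. Markers of other cell types gave 0.375 for leukocytes, 0.558 for fibroblasts and stellate cells and 0.58 for endothelium and cholangiocytes.

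Changes in the pair of arrays numbered 1 (exposure minus DMSO) correlated across genes with those in the pair numbered 2 at 0.254 for benzo[a]pyrene, 0.434 for CCCP, 0.28 for FCCP, 0.372 for dinoterb and 0.451 for TCP. In pairs 1 and 2, CCN1 rose by 1.39 and 3.11 with dinoterb and by 2.01 and 3.50 with TCP. DUSP1 rose by 1.70 and 2.91 with dinoterb and by 2.24 and 3.14 with TCP. The gene counts rest on a spread pooled over all 7 groups. With only the compared groups in the fit, 9 genes passed for benzo[a]pyrene and 0 for CCCP, FCCP, dinoterb and TCP, with 2283, 2681, 2292, 2772 and 3076 at an unadjusted p under 0.05. With arrays numbered 1 left out, which leaves 1 array per exposure, 0 genes passed in any comparison in limma, with 1312, 2936, 2853, 3089 and 3173 at an unadjusted p under 0.05. When dim probes were kept, 13, 48, 40, 54 and 225 genes passed, and with DMSO and medium arrays pooled as the control 35, 802, 945, 961 and 1523. On hg19 the probe of CYP1A1 lies on chromosome 15 at 75012562 to 75012621, that of TIPARP on chromosome 3 at 156424310 to 156424369, that of PFKFB3 on chromosome 10 at 6277062 to 6277121 and that of DDIT3 on chromosome 12 at 57911200 to 57911526.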

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

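Named genes passed in 159 results, a gene counted once in each comparison where it passed. None of these turned direction under any alternative except for GRIP2, for which keeping dim probes took another probe, at -0.07 in FCCP minus DMSO and -0.023 in FCCP minus CCCP. Their calls were kept for 148 with all probes tested, 134 with quantile normalization, 128 with normexp, 134 in the deposited table, 144 with trend and robust eBayes, 152 with the replicate block (7 lost, 8 others gained), 63 without a filter and 6 with only the compared groups in the fit. Slide as a block kept 114 (45 lost), and both blocks together kept 88 (71 lost). Of the 43 list calls, 35 were kept with quantile normalization, 35 with normexp, 30 without a filter and 11 with an estimated correlation. The fits by slide, with both blocks, with either block for the gene lists, with the replicate block without benzo[a]pyrene, without arrays numbered 1 and with equally numbered pairs were chosen after seeing the data. Where a count moved, the cause was not tested, except that some settings leave less power by construction. These are 1 array per exposure, the 8 arrays of 1 slide, 2 groups in a fit, and 33600 tested genes without a filter. Within-slide values cannot be had where a slide lacks a group, and the block without benzo[a]pyrene gives none for that exposure. Signal over background limits dim genes: 51.7% to 64.2% of probes were well above it. A lone array left in a group is assumed to vary like the other groups.

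Counts of genes are given for benzo[a]pyrene, CCCP, FCCP, dinoterb, TCP and FCCP minus CCCP in this order, where they moved by over 1.5 times. With the replicate block, CCCP, FCCP, dinoterb and TCP had 683, 795, 855 and 1501 and FCCP minus CCCP 2. With the replicate block without benzo[a]pyrene they had 1050, 1271, 1351, 2096 and 1. With replicate and slide blocks together benzo[a]pyrene had 10, FCCP 38, dinoterb 90, TCP 1188 and FCCP minus CCCP 0. The replicate block gave 16 lists for benzo[a]pyrene and 1 for DMSO minus medium and ended the hypoxia and clock calls of dinoterb, and changed no other list call among the 43. With slide as a block CCCP had 112, FCCP 170 and FCCP minus CCCP 1, and ribosomal proteins turned lower in FCCP minus CCCP (0.594). On slide 1 benzo[a]pyrene had 9, CCCP 6, TCP 2 and DMSO minus medium 7 genes, with 1 list for benzo[a]pyrene, 6 for DMSO minus medium and cholesterol turned lower with benzo[a]pyrene (0.832). On slide 2 FCCP and dinoterb had 0 and TCP 2 genes, and DMSO minus medium 5 lists.

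With DMSO and medium arrays pooled the 5 exposures had 35, 802, 945, 961 and 1523 genes. Without a filter the counts were 13, 48, 40, 54, 225 and 2, and the lists 5 for benzo[a]pyrene, 9 for FCCP, 13 for dinoterb and 1 for FCCP minus CCCP. With normexp benzo[a]pyrene had 37, dinoterb 548 and FCCP minus CCCP 0, with 2 lists in the last, and secretory markers turned upwards with benzo[a]pyrene (0.955). Quantile normalization gave dinoterb 398 and FCCP minus CCCP 2 lists. The deposited table gave benzo[a]pyrene 34, dinoterb 446 and FCCP minus CCCP 2. FCCP minus CCCP had 0 with trend and robust eBayes and 0 with the stricter filter. With only the compared groups, benzo[a]pyrene had 9 and the others 0. Without arrays numbered 1 all had 0, with 2, 11, 8 and 14 lists for benzo[a]pyrene, CCCP, FCCP and dinoterb, 3 for DMSO minus medium, and cholesterol turned lower with benzo[a]pyrene (0.48). An estimated correlation gave 1, 3, 3, 0, 4 and 0 lists.

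Leaving out each array in turn gave 6 to 14, 26 to 111, 48 to 299, 4 to 106, 86 to 725 and 2 to 18 genes, and 0 to 2 for DMSO minus medium. Lists ranged over 3 to 13, 9 to 15, 5 to 10, 6 to 14, 8 to 14 and 7 to 13, and 1 to 7 for DMSO minus medium. Adjusted p ranged from 0.00102 without DMSO replicate 3 to 0.97 without DMSO replicate 1, where it turned lower, for cholesterol genes with benzo[a]pyrene, and from 1.32e-10 without CCCP replicate 1 to 0.729 without CCCP replicate 2, where it turned lower, for ribosomal proteins in FCCP minus CCCP.

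Correlations of changes moved with the controls. With medium for the first exposure they were -0.061, -0.185, -0.273 and -0.073 for benzo[a]pyrene with CCCP, FCCP, dinoterb and TCP (TCP 0.057 with DMSO for both), 0.464 and 0.59 for CCCP with dinoterb and TCP, and 0.385 and 0.519 for FCCP with dinoterb and TCP. With medium for the second they were -0.138, -0.307, -0.324 and -0.179 for benzo[a]pyrene with CCCP, FCCP, dinoterb and TCP, 0.517, 0.463 and 0.536 for CCCP with FCCP, dinoterb and TCP, and 0.518 for dinoterb with TCP. In equally numbered pairs with the first against DMSO they were -0.139, -0.255, -0.251 and -0.173 for benzo[a]pyrene with those 4, 0.482, 0.389 and 0.488 for CCCP with the other 3, and 0.422 for FCCP with dinoterb. With the first against medium in such pairs they were -0.066 for benzo[a]pyrene with CCCP, and 0.552, 0.494 and 0.498 for CCCP, FCCP and dinoterb with TCP.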

Other observations

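The tests of slide, brightness, short-lived messages, lower receptor activity and carried-over material were chosen only after the results they measure were seen.

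Arrays numbered 1 differed from the other arrays of their group in the 6 groups other than benzo[a]pyrene, in controls and exposures alike. NPPB, a natriuretic peptide gene, was 3.47 ± 0.11 higher on the log2 scale, IGFBP3, a binding protein of insulin-like growth factors, 3.24 ± 0.18, MMP7, a matrix metalloproteinase, 3.16 ± 0.11, and KRT17, a keratin, 2.82 ± 0.17 (SE of the limma fit, n = 6 against 8 arrays). ANKRD1 (2.10) and TAGLN (2.06), targets of YAP and of serum response factor, were higher too. HMGCS1, an enzyme of cholesterol synthesis (-2.05 ± 0.11), and MMAB (-2.32 ± 0.07) were lower. These errors, and the p-values of the lists below, treat the arrays as separate replicates. If arrays of 1 number shared a culture or day of work, they do not measure the spread between cultures or days.

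By list, 23 of 24 cholesterol genes were lower (median -1.13, camera adjusted p = 9.18e-19, and 0.0153 with an estimated correlation), as were 22 of 22 S phase genes (-1.03, 2.21e-18, and 0.0153). Hypoxia targets were higher in 23 of 25 (median 0.75, adjusted p = 1.28e-12, and adjusted p = 0.0998 with an estimated correlation), and 20 of 22 G2/M genes were lower (-0.43, 1.6e-10, and 0.121). In limma 3805 genes were higher and 3710 lower, and in the 6 control arrays alone 1168 and 1399. The differences in controls and in exposures correlated at 0.693 across 19629 genes.

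The common deviation of arrays numbered 1 was weighed against a pair of technical sources. Slide does not account for it, since an array numbered 1 lay at least 39.5 from another of its group on the same slide on the first component, while arrays numbered 2 and 3 on different slides lay at most 4.3 apart. Overall brightness does not either, since the lowest correlation of residuals between arrays numbered 1 was still 0.21 after quantile normalization. A separate culture or day of work stays open, and the labels name none. No biological explanation was tested.

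The fall of CYP1A1 with CCCP and FCCP was not a matter of scaling, since its smallest fall over both exposures and both quantile scalings was -1.77 and passed the threshold. A general loss of short-lived messages would lower the KRAB zinc finger genes as well. The test asked for medians of -0.55 and -0.49 or lower, a chosen fraction of the fall of CYP1A1. Their medians were -0.12 ± 0.07 and -0.21 ± 0.06, the lower being -0.214. Here ± is the SE of a median over genes, which are not replicates. These values argue against a general loss of that size. A weaker loss stays open, since the list shifted downwards with FCCP at the preset correlation. Lower activity of AhR may contribute and cannot be told apart from a loss of the CYP1A1 message alone. The 10 other targets measured in DMSO had medians of 0.18 ± 0.38 and 0.24 ± 0.34 (0.245 at most) and went both ways.

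Shared DMSO arrays do not account for the rise with both benzo[a]pyrene and TCP of 7 of the 10 shared genes. These stayed past the threshold in both with different control arrays, and the others did not. Residuals of equally numbered DMSO and medium arrays correlated at 0.315 to 0.542. A deviation common to both kinds of control is thus not removed by this exchange. The tables argue against material or a label of a benzo[a]pyrene array on 1 TCP array as the whole cause: the 15 genes raised by benzo[a]pyrene against medium lay above DMSO of the same slide by a median of 0.94 ± 0.41 on the TCP array of slide 1 and 1.41 ± 0.39 on that of slide 2. These errors are the SE of a median over the 15 genes and do not measure the spread between arrays. The rule used, above 0 by more than 2 standard errors on both arrays, was the last of 4 written after the values were seen, and of the other 3 only the first, on genes picked for the pattern, came out alike. The other 2 left it open, with bounds of 1.08 for the 1.41 and 0.54 for the 0.94 that lay within the error, so a part of the rise from such material, or material on both TCP arrays, stays open. Another candidate explanation is that TCP, or something in its preparation, activated AhR. Its test, planned before the result was seen, gave a median change of 1.17 with TCP for these 15 genes, 14 of them higher and 7 past the threshold. The genes were picked on the same benzo[a]pyrene arrays and scored on the same TCP arrays as the shared genes. These values thus restate the pattern and cannot tell this explanation from carried-over material.

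For DMSO minus medium, the 10 splits of the 6 control arrays are too few for a share under 0.05. The real split gave 0 genes in limma and the highest of the others 0, so that 10 of 10 gave as many, which a count of 0 fixes in advance. At an unadjusted p under 0.05 the real split had 252 genes. The 3 other splits that part every pair of equally numbered arrays had 172 to 245, the 4 that put both arrays numbered 1 together had 716 to 940, and the other 2 had 185 and 827. Counts several times the real one point to a structure of the samples, which pairing by number does not fully describe, since the split with 827 kept the arrays numbered 1 apart. That split is the one by slide: DMSO controls 1 and 3 and medium control 3 lay on slide 2, and the other control arrays on slide 1.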
